A study of Mus musculus with 12 samples.

How the data were processed

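Each of 12 mouse RNA samples was hybridised to 1 one-colour Agilent array with probes of 60 bases. The groups, taken from the labels, were ES cells, MEF, Bmi1-transduced neural stem cell-like spheres and 5 groups of iPS lines, 9 lines in all. The sphere sample is called an iPS sample in its description field and a neural stem cell-like sample elsewhere in its labels; the latter was used. The deposited intensity values are processed signals that Agilent Feature Extraction 9.5.3.1 made from scans at 5 microns per pixel, after background subtraction and before any scaling between arrays, per the file headers. The deposited flags, also written by Feature Extraction per the file headers, say whether a spot was well above background, saturated or an outlier. Other steps before deposition are not given in the sources used here.

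Of 45018 spots per array, 43379 were gene spots, for 41174 probes. Outlier spots were left out and replicate spots averaged as log2 processed signal, from which the array's 75th percentile was subtracted. A probe was kept if well above background on at least 1 array, and each gene was represented by its probe with the highest mean signal; 8316 genes had several probes. Names came from a RefSeq table, through the accession for 23075 probes and through the symbol or a synonym for 9659, and the deposited name was kept for 8440. Probe positions are in the mm7 build of the array design. This left 25199 genes. Where a gene was dim on all arrays of a group, its change is given as a bound, with each signal of that group raised to its array's floor. The floor was the lowest signal among probes well above background on that array, and ran from -7.27 to -4.2 log2 units. The percentage of spots well above background is the depth of each array.

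The iPS lines as 1 class were compared with MEF and with ES in a limma model of 4 classes with 8 residual degrees of freedom. The iPS groups were compared with each other in a model of 8 groups with 4 residual degrees of freedom. Empirical Bayes variances and Benjamini-Hochberg adjusted p-values were used, with a threshold of 0.05. A group of 1 array was assumed to vary as the others do. Spheres against MEF and ES against MEF, 1 array against 1, had no test, and genes at least 2-fold apart and well above background in the higher sample were counted. No comparison had 3 samples or more in each group, so other splits of the samples were not counted. Clone numbers in the titles did not pair the samples.

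The 28 gene lists had 567 of 580 members on the array: pluripotency, fibroblast, epithelial, mesenchymal regulators, neural stem, neurons and glia, hedgehog pathway, polycomb components, Ink4, Arf and p53 targets, Hox, cholesterol synthesis, LXR targets, mitosis and replication, primitive endoderm, trophectoderm, mesoderm and epiblast, endothelium, blood and immune, muscle, keratinocyte, Dlk1-Dio3 cluster, other imprinted, X-inactivation and Y-linked, germline and 2-cell stage, interferon-stimulated, stress response, glycolysis and control genes. They were tested with camera at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the lists of a comparison, and again with an estimated correlation. Of 168 such tests 21 passed with the preset value and 4 with the estimated one. In comparisons of 1 array against 1, a list's median was ranked among those of 10000 random lists matched in 20 bins of expression.

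Comparisons, lists, main alternatives and the rule for named genes were fixed before the data were examined. The rule names Bmi1, Pou5f1, Sox2 and Nanog everywhere, the 10 genes with the largest change each way that passed, were well above background on every array of the higher group and had a proper gene symbol, and up to 4 members of each list with the largest change among those that passed or were at least 2-fold apart. Beyond the rule, members that did not pass were named as examples after their values were seen, as was the second Bmi1 probe. Slc1a3, named for iPS lines against MEF, was also outside the rule.

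Alternatives were normexp background with an offset of 50, quantile normalization, scaling on probes detected on all arrays, no filter or one requiring 6 arrays, the mean of all probes, an intensity trend in the variances, slide as a fixed or random block, fits within a slide, the 8-group model, leaving out the tail-tip lines or each line in turn, a clone-number block, and a 3-fold threshold or pooled limma spread for single arrays. Leaving out the 3 lines nearest to MEF, raising dim signals to the highest array floor, a slide term for the spheres and fits within the slide of the Shh-Oct4 line were chosen after seeing the data. The fit was tested on simulated data with 200 changed genes of 25199. Simulated noise took each gene's spread from the 4-class model in every comparison. That spread also holds differences between the iPS groups, so for comparisons between these groups the shares found apply to that spread only. R 4.3.3, limma 3.58.1, Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9 were used.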

Results

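RNA from 12 mouse samples was measured on 12 one-colour (Cy3) Agilent gene expression arrays, 1 array per sample. The reference samples were embryonic stem (ES) cells from 129/Ola mice and mouse embryonic fibroblasts (MEF), each on 1 array. A further array held neural stem cell-like spheres grown from fibroblasts transduced with Bmi1, a subunit of the Polycomb repressive complex. The other 9 arrays held induced pluripotent stem (iPS) lines, all made with the transcription factor Oct4 (Pou5f1). Of these lines, 2 were made from embryonic fibroblasts with Bmi1 and Oct4. A further 5 came from embryonic fibroblasts given an activator of the hedgehog pathway before Oct4: 1 line with the protein Shh, 2 with oxysterol (an oxidised cholesterol derivative) and 2 with purmorphamine (a synthetic agonist of Smoothened). The last 2 lines were made with oxysterol and Oct4 from adult tail-tip fibroblasts. ES, MEF, the spheres and the Shh-Oct4 line had no replicate. The 75th percentile of the processed signal ran from 1340 intensity units on the array of oxysterol-Oct4 line 1 to 2156 on that of tail-tip line 1. Between 58.4% of spots (Shh-Oct4 line) and 80.0% (spheres) lay well above background, against 72.8% for MEF and 64.9% for ES. The number of arrays limits the precision of every value.

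Over the 25199 genes tested, the iPS lines lay close to ES. Their Pearson correlations with ES, across genes within arrays, ran from 0.907 (oxysterol-Oct4 line 1) to 0.936 (purmorphamine-Oct4 line 1). Their correlations with MEF ran from 0.805 to 0.861. Those closest to MEF were tail-tip line 2 (0.861), purmorphamine-Oct4 line 2 (0.856) and Bmi1-Oct4 line 1 (0.839). The spheres stood apart from both references, with a correlation of 0.843 with MEF and 0.806 with ES. ES and MEF correlated at 0.815. Genes are not independent replicates, so these values carry no test.

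**Figure D1:**
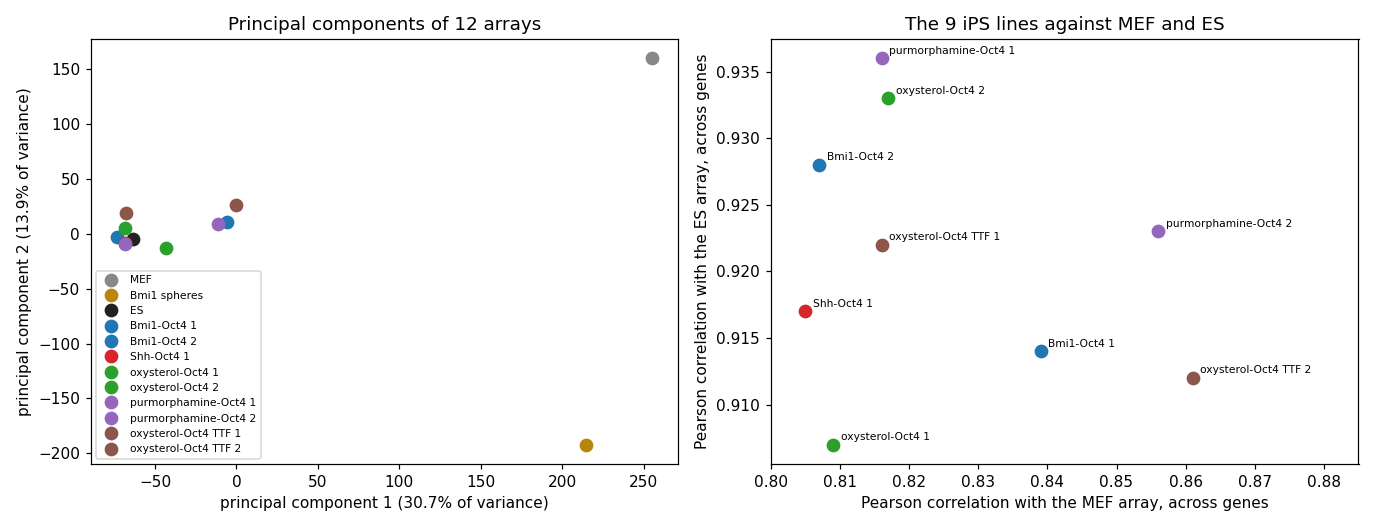
Left, the 12 arrays on their first principal components, which held 30.7% and 13.9% of the variance over genes. Right, each of the 9 iPS lines by its Pearson correlation across genes with the MEF array (x axis) and the ES array (y axis); 3 lines lie nearest to MEF, at 0.839, 0.856 and 0.861.

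The first comparison, of the 9 iPS lines with MEF, asks how far the lines had left the fibroblast state. Core pluripotency genes were higher in the lines. Pou5f1 was 10.35 log2 units higher than in MEF (SE 0.417, adjusted p = 4.41e-07), Nanog 8.85 (SE 0.483, adjusted p = 3.07e-06) and Sox2 5.03 (SE 0.437, adjusted p = 6.53e-05). All lines were given Oct4, and the vector sequence was not at hand, so Pou5f1 values here and below do not separate transgene RNA from RNA of the cell's own gene. Nanog was saturated in ES and in 6 of the 9 lines, so its differences here and below rest partly on signals at the top of the scale. The epithelial adhesion gene Cdh1 rose at least 729-fold, while the fibroblast matrix gene Postn fell at least 79.3-fold. With limma and the Benjamini-Hochberg correction, 2074 genes rose and 700 fell, every one of them by more than 2-fold, and the smallest adjusted p was 7.26e-08.

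Of 35 measured pluripotency genes, 25 rose and none fell (29 rose adjusted over the list alone). Zfp42, the marker also called Rex1, rose at least 1680-fold and Lin28a, an RNA-binding blocker of let-7 microRNA processing, at least 534-fold. Sall4, a zinc finger factor of early embryos, rose by 11.46 log2 units, with saturated spots in 8 lines. Klf4 (-0.08) was among the 10 that did not pass. Of 18 germline and 2-cell stage genes, 12 rose (15 adjusted over the list alone). Among them Mael, a piRNA pathway gene, rose at least 263-fold, Stra8 at least 193-fold and Stk31 at least 51.3-fold. Dazl rose at least 132-fold, although a second Dazl probe lay at -2.49. Camera called the pluripotency list higher (median 5.03, adjusted p = 7.9e-23) and the germline list higher (median 5.30, adjusted p = 1.46e-10). With an estimated correlation between genes both calls held (adjusted p = 0.026 and adjusted p = 0.04 with an estimated correlation).

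Cells also exchanged mesenchymal for epithelial transcripts. Of 21 epithelial genes, 11 rose and none fell (12 adjusted over the list alone). The tight-junction gene Cldn7 rose at least 833-fold, the desmosomal gene Pkp3 at least 234-fold and the polarity gene Crb3 at least 58.4-fold. Krt19 (-0.44) did not pass. Of 32 fibroblast genes, 9 fell (15 adjusted over the list alone). Fap, a surface protease of activated fibroblasts, fell at least 38.9-fold. Fbn1, which encodes microfibrils, fell by 5.40 log2 units, and Col5a2, above background in 4 of the 9 lines, fell at an adjusted p of 0.0499. Other matrix genes did not pass, either because the lines differed widely, as for Dcn (above background in 4 of the 9 lines), or because the change was small, as for Col1a1 (-0.55). Of 16 mesenchymal regulators 4 fell (13 adjusted over the list alone): Tgfb2 by 4.68 log2 units, Snai2, which represses Cdh1, by 4.48, Prrx2 by 2.69 and Cdh2 by 2.63. Of 37 Hox genes, which pattern the body axis, 3 fell (1 adjusted over the list alone): Hoxc8 at least 19.7-fold, Hoxc6 by 3.08 log2 units (above background in 8 of 9 lines) and Hoxb2, above background in 5. The epithelial list was called higher (median 3.44, adjusted p = 3.82e-08; adjusted p = 0.04 with an estimated correlation). The Hox list was called lower (median -1.49, adjusted p = 3.7e-06; adjusted p = 0.0367 with an estimated correlation). The fibroblast (median -4.10, adjusted p = 2.88e-13) and mesenchymal regulator lists (median -4.12, adjusted p = 3.68e-09) were called lower, but with adjusted p = 0.0611 for each with an estimated correlation. Fibroblast genes were highest in tail-tip line 2, at a list median of 1.67 over ES, and in purmorphamine-Oct4 line 2, at 1.13, against -0.13 to 0.61 in the other 7 lines.

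**Figure D2:**
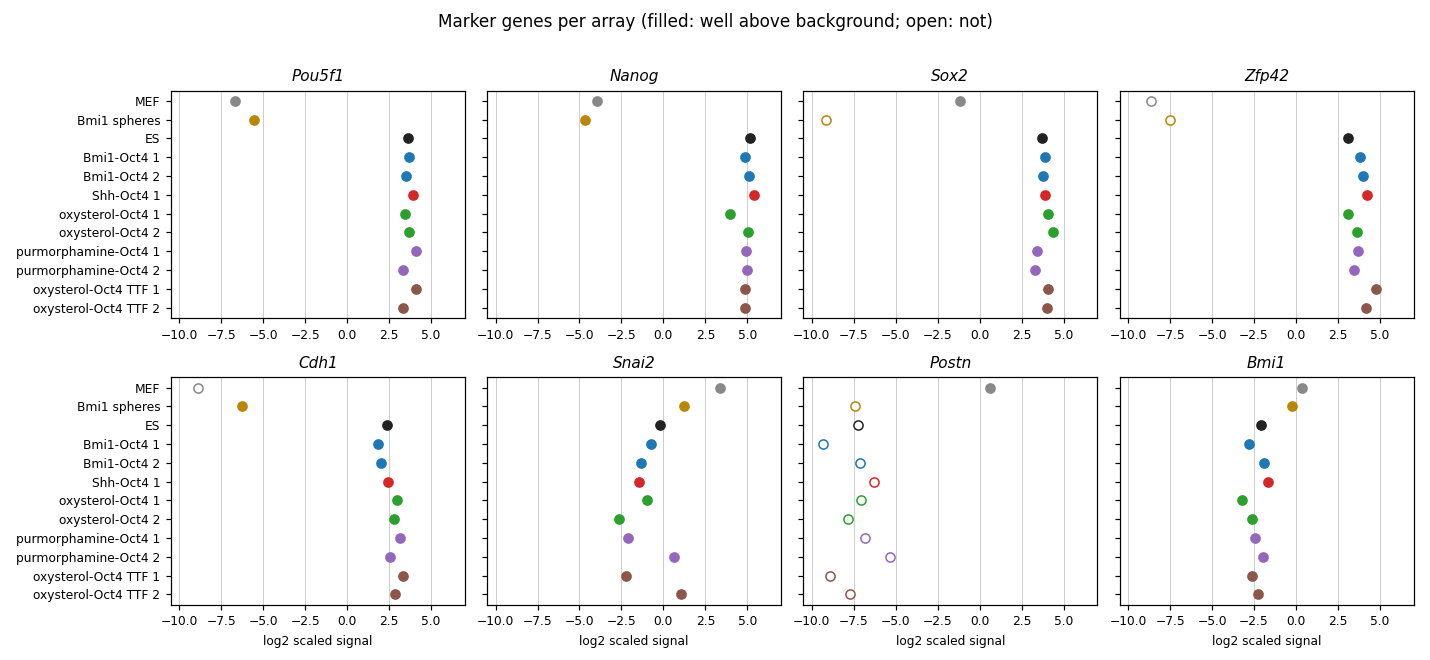
Scaled log2 signal (x axis) of marker genes on each of the 12 arrays (y axis), with colours for the groups. Filled points were well above background and open ones were not; the pluripotency genes and Cdh1 sit together in ES and the iPS lines, and Postn was well above background in MEF alone.

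Some polycomb genes rose. Of 25 measured components, 9 rose and 1 fell (9 rose and 3 fell adjusted over the list alone). Phc1 rose by 5.69 log2 units, Cbx7, a chromodomain subunit, by 5.64, Pcgf2, a paralogue of Bmi1, by 5.42, and Pcgf5 by 4.78 (saturated in 3 lines), although its second probe lay at -2.41. Bmi1 itself fell by 2.76 (SE 0.548, adjusted p = 0.0102) on the probe with the higher signal, on chromosome 2 at 18751519 to 18751578 of the mm7 build. Its other probe, in the Bmi1 coding sequence at 18748838 to 18748897, lay higher in the lines than in MEF but was above background in only 4 of the 9, so the direction rests on the probe. The polycomb list was not called (adjusted p = 0.0971). Of 20 Ink4, Arf and p53 target genes only Perp fell (-2.54, saturated in MEF; none adjusted over the list alone), and Cdkn2a (-3.13) and Cdkn2b (-3.68), the cell-cycle brakes of the Ink4 locus, did not pass. That list was called lower (adjusted p = 0.03; adjusted p = 0.267 with an estimated correlation). Of 30 mitosis and replication genes 7 rose (18 adjusted over the list alone), among them the spindle checkpoint kinases Bub1b (2.88) and Bub1 (2.13) and the replicative helicase subunits Mcm5 (2.53) and Mcm2 (2.28). That list was called higher (median 1.38, adjusted p = 0.000105; adjusted p = 0.267 with an estimated correlation).

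The lists for the hedgehog pathway and the neural lineage were mixed. Of 19 hedgehog pathway genes 2 rose, among them Mycn (6.50), while Smo fell by 1.87 on its brightest probe; its other probes were dim in MEF or in most lines (2 rose and 2 fell adjusted over the list alone; list adjusted p = 0.65). Of 32 neural stem genes 4 rose, among them the glutamate transporter Slc1a3 (2.59), Sox2 and Pax6 (at least 12.6-fold, above background in 7 of 9 lines). Pax6 had probes more than 2-fold apart in opposite directions, so its rise rests on the probe used. Gfap, above background in 4 lines, fell on the probe used (4 rose and 1 fell adjusted over the list alone, list adjusted p = 0.635). Of 18 genes of neurons and glia 5 rose (7 adjusted over the list alone), among them the myelin gene Mog (at least 37.8-fold), with a list adjusted p = 0.0331 (adjusted p = 0.168 with an estimated correlation). Of 13 trophectoderm genes Tfap2c (7.64, saturated in 2 lines) and Eomes (5.17) rose (2 adjusted over the list alone; list adjusted p = 0.00899; adjusted p = 0.168 with an estimated correlation). None of 21 interferon-stimulated genes passed, nor did any adjusted over the list alone, but their list lay lower (median -2.73, adjusted p = 6.16e-05; adjusted p = 0.32 with an estimated correlation). Among cholesterol-linked genes, Apoe, a target of the oxysterol receptor LXR, fell by 4.93 (1 of 15 LXR targets, and 1 adjusted over the list alone; list adjusted p = 0.0232; adjusted p = 0.197 with an estimated correlation). Of 25 cholesterol synthesis genes Hsd17b7 fell by 1.89 (none adjusted over the list alone; list adjusted p = 0.123).

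The remaining lists were not called, and their counts were the same adjusted over the list alone unless given. Of 21 primitive endoderm genes 3 rose, among them the laminin gene Lama1 (at least 148-fold), and 2 fell, among them the collagen gene Col4a2 (-3.09; 4 rose and 5 fell adjusted over the list alone). In the mesoderm and epiblast list of 15, Otx2 rose at least 27.1-fold and Hand2 fell by 2.38. Of 13 endothelial genes 4 rose, among them the receptor Tek (at least 41-fold; adjusted over the list alone 1 gene fell as well). Laptm5 (7.30) and Hba-a1 (2.89) rose among 15 blood and immune genes. Mylpf (5.91) and the filament gene Des rose and Actc1, above background in 2 lines, fell among 11 muscle genes. Perp was the only faller among 10 keratinocyte genes. Phlda2 (5.42), Snrpn (2.99) and Peg10 (2.69) rose and Gnas fell among 24 imprinted genes, and Gnas had other probes at 2.31 and 2.33. No gene of the 5 measured in the imprinted Dlk1-Dio3 cluster passed. Xist rose by 3.12 on its brightest probe and lay lower on the other 3, at -3.47 on the one above background in 8 of 9 lines, among 11 X-inactivation and Y-linked genes. Fosb (3.61, saturated in 5 lines) rose among 17 stress genes. Slc2a3 (5.95, with saturated spots in the lines), Pfkp (3.06) and Hk2 (1.44) rose among 20 glycolysis genes. Tfrc (2.37) and Polr2a (1.77) rose among 18 control genes.

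Outside the lists, the largest rises above background in all 9 lines included the ES-cell RNA Platr10 (at least 4030-fold), Ccdc88c (at least 3060-fold), Pla2g1b (at least 1600-fold), the chromatin remodelling subunit Cecr2 (at least 1430-fold) and Hook1 (at least 1020-fold). Several of the largest fitted falls were in genes above background in only some lines, so their sizes rest partly on signals below the array floors and are not given. They were Rgs4 (above background in 5 lines), Fibin (4 lines), Cck (3), Qsox2 (3), Olr1 (2), Mcpt8 (1), Ccn5 (1), Frzb (1) and Ccl20 (1). Cck had probes more than 2-fold apart in opposite directions, so its fall rests on the probe used. Of the called genes, 631 of those higher and 84 of those lower are bounds, since they were dim in MEF or in all the lines.

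MEF was 1 array, assumed to vary as the iPS lines do, and p-values here and elsewhere measure only the spread between these samples. Genes as a whole lay 0.436 log2 units higher in the lines (0.157 with quantile normalization) while the control genes lay at 0.003, and 74.8% of calls were higher, against 64.4% with quantile normalization, 62.4% with normexp background and 56.5% (1604 higher, 1233 lower) with signals raised to the highest array floor, a setting chosen after seeing the data. MEF shared its slide with ES and the Bmi1-Oct4 lines; with slide as a fixed block 1324 genes rose and 478 fell, the medians were 4.99 for pluripotency, -4.25 for fibroblast and 2.98 for epithelial genes, and 23 of the 90 named genes missed the threshold, among them Bmi1 (adjusted p = 0.0566), Snai2, Tgfb2, Prrx2, Cdh2, Pcgf2 and Pcgf5. Within that slide Pou5f1 lay at 10.25, Nanog at 8.94, Sox2 at 4.99 and Bmi1 at -2.72, with 0 genes past the limma threshold on 1 residual degree of freedom. Each group of 2 lines gave calls against MEF: 1056 higher and 400 lower for Bmi1-Oct4, and 1188 and 344 for oxysterol-Oct4. The counts were 850 and 150 for purmorphamine-Oct4, and 905 and 206 for the tail-tip lines. The Shh-Oct4 line against MEF was 1 array against 1, on different slides, so its calls are not given. Differences between these counts were not tested.

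The comparison of the 9 iPS lines with ES asks how near the lines came to embryonic stem cells. Few genes separated them. Pou5f1 (0.06, SE 0.417), Sox2 (0.16, SE 0.437), Nanog (-0.26, SE 0.483, saturated in ES and in 6 lines) and Bmi1 (-0.30, SE 0.548) all had an adjusted p of 1. With limma, 2 genes were higher and 5 lower in the lines, while 1135 had an unadjusted p under 0.05 where chance gives 1260. The cytoskeletal gene Dtna rose at least 21.6-fold (adjusted p = 0.0203; another probe lay at -0.67) and Rasd2, a Ras-like GTPase, at least 10.3-fold (adjusted p = 0.0248). Espl1, which encodes the protease separase, fell by 4.68 (adjusted p = 0.0418), and the olfactory receptor gene Olfr172 fell at least 16.5-fold (adjusted p = 0.0381). Myo16 (adjusted p = 0.0381) and Wdr5b (adjusted p = 0.0418) fell and were each above background in 3 of the 9 lines. The remaining gene was a probe with no gene name.

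No list gene passed over all genes, and adjusted over the list alone 1 endothelial gene rose. Primitive endoderm genes lay lower as a list (median -0.64, 14 of 21 below ES; adjusted p = 0.0211; adjusted p = 0.337 with an estimated correlation), with Cubn at -3.77 and Sox17 at -2.78. Interferon-stimulated genes lay higher (median 1.06, 19 of 21 positive, adjusted p = 0.0211; adjusted p = 0.723 with an estimated correlation), with Ifit1 at least 11.9-fold above ES and not past the test for a single gene. With slide as a fixed block the primitive endoderm list was not called (median -0.41, adjusted p = 0.243) and the interferon list was (median 2.07, adjusted p = 0.000653). The interferon signal was highest in the lines nearest to MEF: the list lay 3.22 above ES in Bmi1-Oct4 line 1, 2.42 in tail-tip line 2 and 1.77 in purmorphamine-Oct4 line 2, against -0.15 to 0.87 in the other 6. Without those 3 lines, a setting chosen after the data were seen, its adjusted p was 0.315. The other lists were not called, from neural stem, blood and immune, and X-inactivation and Y-linked genes (adjusted p = 0.0528 each) to polycomb genes (adjusted p = 0.874).

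ES was 1 array, and the median 95% interval was 3.28-fold either way, so smaller differences were not detectable. In simulated data of this design, 40.9% of 16-fold and 1.5% of 4-fold differences were found. All 7 calls ended with slide as a fixed block, with the 8-group model and without the tail-tip lines. They also ended within the slide of ES. That fit had 1 residual degree of freedom and called 0 genes against MEF too, so it decides nothing here. With slide as a random block the count was again 2 higher and 5 lower. Quantile normalization called 7 genes higher and 74 lower, and normexp background 4 higher and 43 lower. Leaving out oxysterol-Oct4 line 1, purmorphamine-Oct4 line 2 or tail-tip line 1 left 0 genes, and leaving out Bmi1-Oct4 line 2, the Shh-Oct4 line, oxysterol-Oct4 line 2 or purmorphamine-Oct4 line 1 left at most 2.

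**Figure D3:**
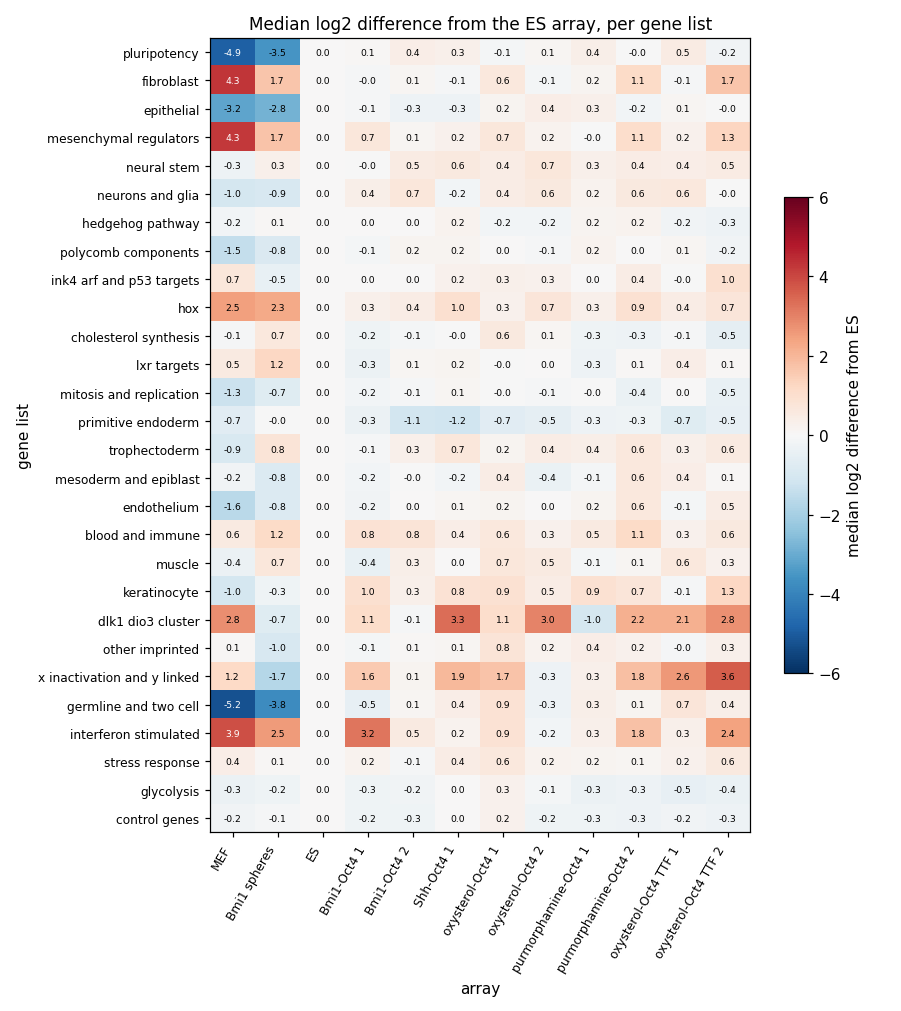
Median log2 difference from the ES array over the measured genes of each of 28 lists (rows) on each array (columns), from blue (lower) to red (higher). MEF lies 4.9 lower for pluripotency genes, and the interferon list is raised in the 3 lines nearest to MEF.

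Bmi1 with Oct4 was set against the hedgehog activators with Oct4, all from embryonic fibroblasts, to ask whether the way of making a line left a mark. No gene passed: limma called 0 genes, with 2488 at an unadjusted p under 0.05 where chance gives 1260, and a smallest adjusted p of 0.112. In simulated data with the spread of the 4-class model, 16.7% of 16-fold differences were found in this comparison. Pluripotency genes lay together (median -0.04, list adjusted p = 0.718), with Pou5f1 at -0.16 (SE 0.404), Nanog at 0.03 (SE 0.409), Sox2 at 0.01 (SE 0.315) and Bmi1 at -0.09 (SE 0.421). The Ink4 locus gene Cdkn2a lay at -3.43 and Cdkn2b at -1.61, and neither passed. Interferon-stimulated genes lay higher in the Bmi1-Oct4 lines (median 0.88, 18 of 21 positive, adjusted p = 0.00504; adjusted p = 0.945 with an estimated correlation), but the list lay 3.22 over ES in Bmi1-Oct4 line 1, among the 3 lines nearest to MEF, and 0.54 in line 2, inside the -0.15 to 1.77 of the hedgehog lines. The Bmi1 probe in the coding sequence read -5.44 and -3.54 in the Bmi1-Oct4 lines and was above background in 1 of the 5 hedgehog lines, at -4.02. Adjusted over the list alone 1 interferon gene was higher, and 2 fibroblast genes and 1 each of the neural stem, Hox, trophectoderm, and mesoderm and epiblast lists were lower. The other lists were not called. Both Bmi1-Oct4 lines sat on the slide of ES and MEF, so slide and method cannot be told apart. With no filter on dim probes 55 genes were called higher and 2356 lower. The median signal of negative control spots was 3.0 and 3.7 on the Bmi1-Oct4 arrays and 7.9 to 21.9 on the hedgehog arrays. These calls can therefore not be told apart from a difference in background.

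Oxysterol and purmorphamine, both small molecules but of different chemical class, were compared in 2 lines each. Cholesterol synthesis genes lay higher in the oxysterol lines as a list (median 0.46, 20 of 25 positive, adjusted p = 0.000868), with Insig1, a sterol-sensing retention protein, at least 5.99-fold higher, Mvd at 1.75 and Fdps at 1.39. Glycolysis genes did too (median 0.44, 19 of 20 positive, adjusted p = 0.00624), with Aldoc at 2.40. Both calls had an adjusted p of 0.765 with an estimated correlation. Oxysterol-Oct4 line 1 stood apart: its median over ES was 0.61 for cholesterol synthesis and 0.28 for glycolysis, against 0.11 and -0.10 in line 2, -0.28 and -0.34 in purmorphamine-Oct4 line 1 and -0.33 and -0.33 in line 2. Control genes were also highest in that line, at 0.24, against -0.24, -0.27 and -0.32 in the other 3. Over MEF, glycolysis in oxysterol-Oct4 line 2 lay at 0.13, between the purmorphamine lines at 0.25 and 0.05. Cholesterol synthesis over MEF lay at -0.15 in that line and 0.48 in oxysterol-Oct4 line 1, against -0.25 and -0.17 in the purmorphamine lines. In the tail-tip lines, also made with oxysterol, it lay at -0.08 and -0.55 over ES, and 0.32 and -0.38 over MEF. No single gene passed: limma called 0, with 1228 at an unadjusted p under 0.05 against 1260 by chance and a smallest adjusted p of 0.872. Pou5f1 differed by -0.16 (95% interval -1.31 to 1.00), Nanog by -0.44 (-1.61 to 0.73), Sox2 by 0.85 (-0.05 to 1.75) and Bmi1 by -0.68 (-1.88 to 0.53). LXR targets (median 0.34) and hedgehog pathway genes (median -0.34) were not called, nor were the other lists, and adjusted over the list alone no list gene passed. The missed tests do not show that the compounds act alike, since the median interval was 2.95-fold either way and no simulated 16-fold difference was found at this size. With slide as a fixed block the medians were 0.62 for cholesterol synthesis and 0.45 for glycolysis, and within the slide of the Shh-Oct4 line limma called 0 genes. Doses and times are not given in the labels.

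Shh, the protein, was set against the small molecules in 1 line against 4. Epithelial genes lay lower in the Shh line as a list (median -0.41, 5 of 21 positive, adjusted p = 0.0254; adjusted p = 0.778 with an estimated correlation). Over ES the list lay at -0.30 in the Shh line, 0.18 and 0.41 in the oxysterol lines and 0.31 and -0.18 in the purmorphamine lines. Over MEF the Shh line was not the lowest, and lay above oxysterol-Oct4 line 1 (3.39) and both purmorphamine lines (3.69 and 3.08). Pluripotency genes (median 0.35) and hedgehog pathway genes (median 0.48) were not called, nor were the other lists. Adjusted over the list alone 1 hedgehog and 1 Hox gene were higher, and 2 epithelial, 2 LXR and 1 neural stem gene were lower. Pou5f1 lay at 0.25 (SE 0.532), Nanog at 0.70 (SE 0.539, saturated in the Shh line), Sox2 at 0.07 (SE 0.415) and Bmi1 at 0.92 (SE 0.554). Limma called 0 genes, with 1595 at an unadjusted p under 0.05 against 1260 by chance and a smallest adjusted p of 0.116, and no simulated 16-fold difference was found. The Shh line was assumed to vary as the other groups do. Quantile normalization called 32 genes and normexp background 2, while the fit with slide as a fixed block and that within the Shh line's slide called 0 each.

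Oxysterol-Oct4 lines from tail-tip fibroblasts were compared with those from embryonic fibroblasts to ask whether the starting cell mattered. X-inactivation and Y-linked genes lay higher in the tail-tip lines as a list (median 2.02, 9 of 11 positive, adjusted p = 0.0227), with the Y-linked genes Uty at 3.30 and Ddx3y at 3.21. Much of this came from oxysterol-Oct4 line 2, where the list lay at -0.32 over ES, against 1.73 in line 1 and 2.59 and 3.63 in the tail-tip lines, and where the scaled log2 signal of Ddx3y was -2.67, against 0.86 in line 1 and 2.39 and 2.22 in the tail-tip lines. Interferon-stimulated genes lay higher (median 1.26, 17 of 21 positive) and glycolysis genes lower (median -0.45, 2 of 20 positive), both with an adjusted p of 0.0235. Glycolysis genes lay at 0.28 over ES in oxysterol-Oct4 line 1, whose control genes were also raised (0.24), and at -0.10 in line 2, against -0.48 and -0.39 in the tail-tip lines. All 3 calls had an adjusted p of 0.839 with an estimated correlation, and no other list was called. Adjusted over the list alone 1 fibroblast and 1 Dlk1-Dio3 gene were higher, and 2 neural stem, 2 imprinted, 1 hedgehog and 1 trophectoderm gene were lower. Pou5f1 lay at 0.13 (SE 0.476), Nanog at 0.38 (SE 0.482, saturated in the tail-tip lines), Sox2 at -0.18 (SE 0.371) and Bmi1 at 0.44 (SE 0.496). Tail-tip line 2, among the lines nearest to MEF, carried the interferon signal (2.42 over ES against 0.30 in tail-tip line 1). Limma called 0 genes, with 1630 at an unadjusted p under 0.05 against 1260 by chance and a smallest adjusted p of 0.385, and no simulated 16-fold difference was found. Both tail-tip lines sat on a slide without oxysterol lines from embryonic fibroblasts, so no within-slide value exists; with slide as a fixed block, through the purmorphamine lines, limma called 0 genes.

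The Bmi1 spheres were compared with MEF as 1 array against 1, with no test, so genes are described by size alone. In the spheres 8298 genes were at least 2-fold higher and 4438 lower, of which 2859 and 1067 are bounds. With normexp background 5112 were higher and 3530 lower, and 79 of the 130 named genes moved in size. Of genes dim in both ES and MEF, 60.4% were well above background on the spheres array, against at most 42.9% on any iPS array. The Bmi1 probe in the coding sequence was 4.99 log2 units higher in the spheres (-1.27 against -6.26 in MEF), while the other Bmi1 probe was 0.60 lower. The vector sequence was not at hand, so this value does not separate RNA of the transgene from RNA of the cell's own gene. Some Ink4, Arf and p53 target genes were lower: Cdkn2a at least 171-fold, Cdkn2b by -7.82 log2 units, Perp by -10.56 (saturated in MEF) and the BH3-only gene Pmaip1 at least 3520-fold. Neural stem genes went both ways, with Pax3 at least 146-fold and Pax6 at least 15.3-fold higher but Sox2 at least 61.1-fold lower. Pluripotency was not in place, with Pou5f1 2.14-fold higher, Nanog at -0.72 and the list at a median of 0.02.

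Of 32 neural stem genes 15 were at least 2-fold higher and 7 lower, a median of 0.85 at percentile 88.18 of 10000 random lists matched on expression. The proteoglycan gene Ncan (3.08) was higher, while Zic1 (at least 508-fold), Prom1 (at least 113-fold) and Slc1a3 (at least 110-fold) were lower; Nes (0.12) did not reach 2-fold. Among 18 genes of neurons and glia 7 were higher, with Erbb3 at 4.34, and 3 lower, with Gap43 at -6.10 (percentile 86.74). Erbb3 had probes more than 2-fold apart in opposite directions, so its rise rests on the probe used. Of 25 polycomb components 11 were higher and 2 lower (percentile 88.32), with Phf1 at 5.37 and Ring1 at 2.68. Of 20 Ink4, Arf and p53 targets 8 were lower and 1 higher, and the list's median was only -0.68 (percentile 0.09), as it was in ES over MEF. Of 32 fibroblast genes 20 were lower and 2 higher (median -2.17, percentile 0), with Postn at least 212-fold, Fap at least 104-fold and Thy1 at -8.10, while Col1a2, saturated in MEF, lay at -0.32. Of 16 mesenchymal regulators 9 were lower (percentile 0), among them Tgfb2 at least 1470-fold. The imprinted Dlk1-Dio3 genes were all lower, 5 of 5 (median -6.05, percentile 0), with Mirg at least 70.7-fold and Meg3 at -7.98, and 12 of 24 other imprinted genes were lower (percentile 0.02), with Igf2 at least 2010-fold. Y-linked genes were near the floor, Ddx3y at least 701-fold and Kdm5d at least 352-fold lower, in a list with 6 lower and 4 higher of 11 (percentile 0).

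Germline genes were higher as a list, 10 of 18 (3 lower, percentile 99.67), with Usp17la at 6.74 and Tdrkh at least 8.92-fold. Mitosis and replication genes were too by their median, 0.578 against 0.371 over all genes (percentile 99.47), with Cdc6 at 2.76. Of these 30 genes 7 were at least 2-fold higher and 1 lower. That is no larger a share higher than the 8298 of 25199 over all genes. Epithelial genes were also higher as a list (percentile 98.61), with 9 of 21 higher, 5 lower and Pkp3 at least 210-fold higher. Interferon-stimulated genes were lower in 11 of 21 (1 higher, percentile 0.02). Hedgehog pathway genes were split, 4 higher and 6 lower of 19 (percentile 16.02), with Gli1 at 2.36. Of 25 cholesterol synthesis genes 5 were higher and 1 lower (percentile 45.58), with Insig1 at 5.93 and Fdps at 4.67. The percentile was 8.14 for Hox genes (9 higher, 10 lower), 70.03 for LXR targets, 95.88 for trophectoderm, 68.76 for primitive endoderm, 15.24 for mesoderm and epiblast, 11.95 for endothelium, 59.22 for blood and immune, 60.63 for muscle, 7.61 for keratinocyte, 17.05 for stress, 80.56 for glycolysis, 86.67 for control and 44.74 for pluripotency genes.

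Among the largest differences above background, beside those given above, were the following. Higher in the spheres were Sult5a1 (at least 722-fold), Padi2 (at least 616-fold), the adhesion adaptor Fermt1 (at least 390-fold), the mast cell tryptase Tpsab1 (at least 289-fold) and the fetal plasma protein Afp (at least 282-fold), followed by Spink8, Platr14, Atp13a4 and Tcp11x2. Lower were Fhl1 (at least 5010-fold), Prss23 (at least 4810-fold), Vgll3 (at least 4550-fold), the growth factor receptor Egfr (at least 2880-fold), Cd24a (at least 2820-fold) and Igfbp5 (at least 2520-fold), followed by Prnd, Fibin and Sulf1. Syn3 was at least 4320-fold lower on its brightest probe, with other probes at 1.63 and 1.64. Genes as a whole lay 0.371 higher in the spheres, which were on another slide than MEF. A limma fit that pooled the spread of the iPS lines called 297 genes higher and 402 lower, and a slide term in that model left 8199 genes higher and 4996 lower by size.

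**Figure D4:**
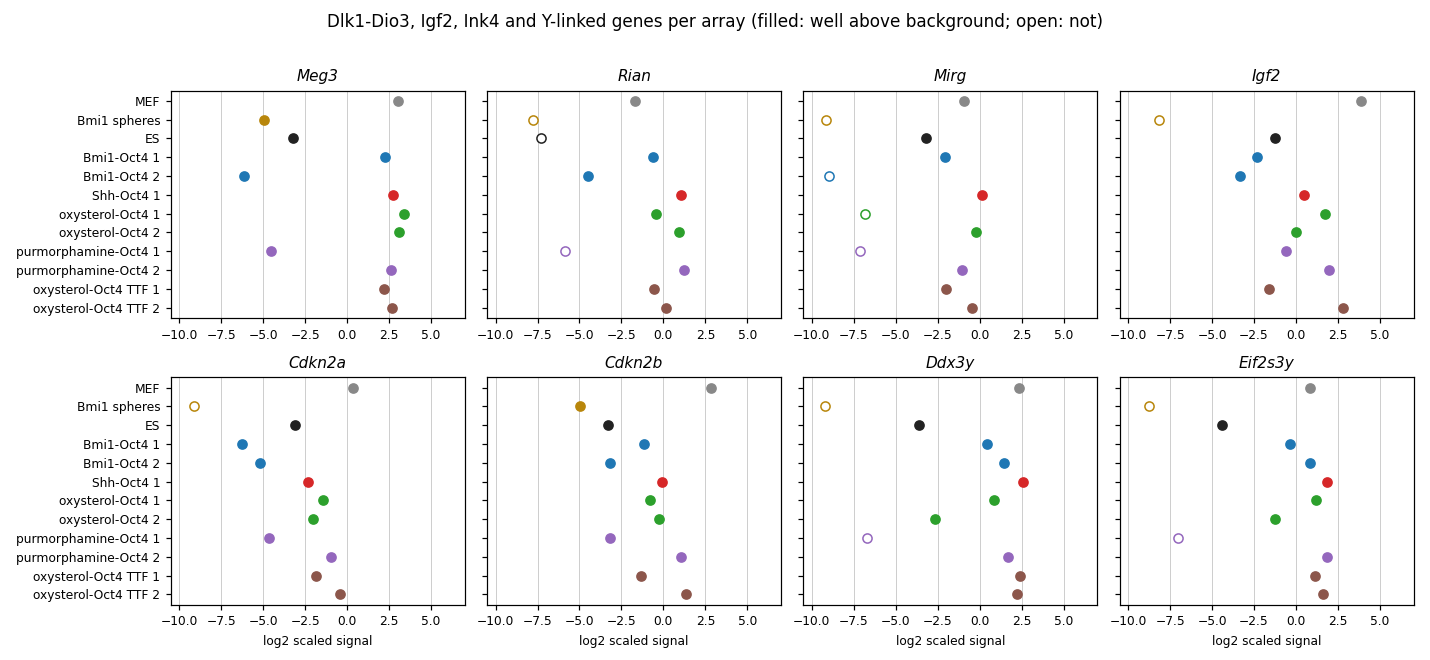
Scaled log2 signal (x axis) of Dlk1-Dio3, Igf2, Ink4 and Y-linked genes on each of the 12 arrays (y axis), filled where well above background. Meg3 lies at -6.13 in Bmi1-Oct4 line 2 and -4.51 in purmorphamine-Oct4 line 1, apart from the other 7 lines, and all 8 genes are low in the spheres.

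ES against MEF, 1 array against 1 and again without a test, served as the reference contrast. In ES 6716 genes were at least 2-fold higher and 5208 lower (1333 and 1650 bounds). Pluripotency genes were higher in 27 of 35 cases (1 lower, percentile 100), with Pou5f1 at 10.28, Nanog at 9.11 (saturated in ES), Sox2 at 4.87 and Zfp42 at least 998-fold. Fibroblast genes were lower in 27 of 32 (percentile 0), with the proteoglycan Dcn at least 993-fold, and mesenchymal regulators in 15 of 16 (percentile 0), with Twist2 at least 1230-fold. Epithelial genes were higher in 16 of 21 (1 lower, percentile 100), with Cldn7 at least 1050-fold, and germline genes in 14 of 18 (percentile 100), with Dazl at least 168-fold on its brightest probe. Hox genes were lower in 24 of 37 (1 higher, percentile 0) and interferon-stimulated genes in 17 of 21 (1 higher, percentile 0), with Ifit1 at least 400-fold. Mitosis genes were higher in 21 of 30 (percentile 99.98), and polycomb genes in 15 of 25 (6 lower, percentile 99.66), with Cbx7 at 5.78 and Bmi1 at -2.47 on its brightest probe. Ink4, Arf and p53 targets were lower in 9 of 20 (2 higher, percentile 0.05), with Cdkn2b at -6.13.

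Among the largest differences, beside those given above, were the following. Higher in ES were Platr10 (at least 3950-fold), Ccdc88c (at least 3460-fold), Fmr1nb (at least 1420-fold), Pla2g1b (at least 1230-fold) and Cecr2 (at least 1190-fold). The sodium channel gene Scn8a (at least 1130-fold), the laminin gene Lama1 (at least 807-fold) and Ildr1 (at least 776-fold) were higher too. Lower were Prss23 (at least 1460-fold), the receptor Il1rl1 (at least 1420-fold), the protease Mmp3 (at least 1300-fold), Rhoj (at least 1290-fold), the matrix glycoprotein Thbs1 (at least 1240-fold), Serpinf1 (at least 859-fold), Mcpt8 (at least 682-fold) and Dnm3os (at least 552-fold). The percentile was 0.48 for Dlk1-Dio3 genes (5 of 5 lower), 10.42 for other imprinted genes, 1.34 for X-inactivation and Y-linked genes, 47.54 for neural stem, 93.59 for neurons and glia, 30.56 for hedgehog, 18.54 for cholesterol synthesis, 2.27 for LXR targets, 80.07 for primitive endoderm, 77.43 for trophectoderm, 30.03 for mesoderm and epiblast, 96.14 for endothelium, 6.28 for blood and immune, 53.38 for muscle, 82.16 for keratinocyte, 0.85 for stress, 69.83 for glycolysis and 43.36 for control genes. Genes as a whole lay 0.394 higher in ES, both arrays shared a slide, and a limma fit that pooled the spread of the iPS lines called 762 genes higher and 155 lower.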

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

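All tests of explanations in this part were chosen only after the results were seen, and some were redefined after their first outcome, as stated where they are given.

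Among 103 values examined over the 9 iPS lines, 9 had a highest or lowest line far from the others by Dixon's gap criterion, where chance alone picks about 1 in 20. Scaled log2 signals were as follows. Apoe lay at -0.45 in oxysterol-Oct4 line 1, above -2.28 to -1.46 in the others. Nanog lay at 3.94 in that line, below 4.86 to 5.42. Eomes lay at -2.73 and Pfkp at 2.06 in purmorphamine-Oct4 line 1, below -1.51 to -0.87 and 3.07 to 3.86. Fosb lay at 2.48 in oxysterol-Oct4 line 2, below 4.17 to 5.61. Otx2 lay at 0.02 in tail-tip line 1, above -3.09 to -1.55, and Sall4 at 5.51 in the Shh-Oct4 line, above 4.76 to 5.13. As a median over ES, the neural stem list lay at -0.02 in Bmi1-Oct4 line 1, below 0.32 to 0.67, and the Ink4, Arf and p53 list at 0.97 in tail-tip line 2, above -0.04 to 0.45. Nanog, Sall4 and Fosb were saturated in 6, 8 and 5 lines, the Shh-Oct4 line among those for Sall4, so their upper values are limited by the scale. These were not tested further. Apart from the genes, the adenoviral E1A control spots were well above background in 99.4% of cases on the spheres array against 28.7% to 58.1% on the others, while its negative control spots were so in 0.7%; the cause was not tested.

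Over 114 genes specific to MEF, the median level as a percentage of MEF was 3.19% in Bmi1-Oct4 line 1. It was 10.1% in purmorphamine-Oct4 line 2 and 16.1% in tail-tip line 2, against 0.166% to 0.429% in 5 of the other lines. The genes were chosen as at least 16-fold higher in MEF than in ES and not above background in ES. The 0.164% in ES therefore follows from that choice. Oxysterol-Oct4 line 1 was also raised, at 2.12%, with Dcn at 2.94% of MEF against 0.106% in Bmi1-Oct4 line 1; its signal was not tested in the same way. A general rise of dim signals on the array was argued against for purmorphamine-Oct4 line 2 and tail-tip line 2, where at most 23.8% of genes dim in both references were above background, below the 39.6% of Bmi1-Oct4 line 2, whose MEF share was low; for Bmi1-Oct4 line 1, at 42.9%, it cannot be told apart. RNA like that of MEF would bring all its abundant transcripts at about 1 share. As the whole source, RNA of this MEF sample was argued against for tail-tip line 2 and, on 4 genes only, for Bmi1-Oct4 line 1. The genes were chosen as high on that 1 array, and fibroblasts of other cultures, tail-tip ones included, had no array. RNA of other fibroblasts can therefore not be excluded. Among genes bright enough for an 8-fold shortfall to be measured, 22.2% of 18 (interval 9.0% to 45.2%) and 12.6% of 95 (7.4% to 20.8%) lay over 8-fold below the line's median share. The highest value between pairs of the other 6 lines, at matched levels, was 7.5% and 5.1%. The intervals treat genes of 1 array as independent, which they are not, so they are too narrow if genes vary together. In Bmi1-Oct4 line 1 the lower end, 9.0%, lay close to the 7.5%. In Bmi1-Oct4 line 1 the 4 genes were Serpinf1, Dcn and Thbd, 40.4-fold, 30.1-fold and 11.6-fold below, and Mcpt8, which was not above background there. For purmorphamine-Oct4 line 2 RNA of this MEF sample stays open, at 7.6% of 66 genes (3.3% to 16.5%) against 5.7%. All 3 limits came from the Shh-Oct4 line paired with oxysterol-Oct4 line 1; without the latter they were 3.9% for Bmi1-Oct4 line 1, 2.3% for tail-tip line 2 and 2.6% for purmorphamine-Oct4 line 2. The criterion was changed more than once. Over all 114 genes the values were 21.1%, 11.4% and 7.0% against limits of 12.3%, 5.6% and 7.4%, or 8.6%, 2.6% and 4.1% without oxysterol-Oct4 line 1. With a doubling of the limit required, those with that line had left Bmi1-Oct4 line 1 and tail-tip line 2 open, and purmorphamine-Oct4 line 2 had lain within its limit; without the interval, tail-tip line 2 had been excluded. A still earlier comparison with brighter genes, not matched in level, had excluded all 3 lines. A median over the fibroblast list was also tried and decided nothing. Incomplete reprogramming was not tested.

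The imprinted RNAs Meg3, Rian and Mirg were low in Bmi1-Oct4 line 2 and purmorphamine-Oct4 line 1, with Meg3 at -6.13 and -4.51 against 2.20 to 3.41 in the other 7 lines. Mirg was also dim in oxysterol-Oct4 line 1 (-6.81, against -7.13 in purmorphamine-Oct4 line 1), and ES was low for all 3 genes, with Meg3 at -3.22, so low levels were not confined to those lines. The pattern did not rest on a single probe, which follows in part from its definition on 3 genes. Of 8 probes, 6, of Meg3 and Rian, put both lines below the other 7 with those above background. The Mirg probe, dim in 3 lines, was not counted, as it had been at first. Fibroblast RNA as the source in the other lines was argued against by Meg3 at 57.1% of its MEF level or more in 3 lines whose share of MEF signal allows at most 1.72%. No biological explanation was tested.

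Cdkn2a and Cdkn2b were far lower in the spheres than in MEF. A generally weak spheres array was argued against by the 22481 genes at the MEF level of Cdkn2b or dimmer. Of these, 86.4% were above background there and 77.7% on the MEF array. The set holds most of the 25199 genes, so it says nothing on weak signal at the probes of these genes alone. Loss of a segment that also holds their neighbours at lower coordinates was argued against by a median of 0.24 over 4 genes. These were the nearest above background and above the highest array floor in MEF, defined after wider sets, with genes near the floor, had been tried. Mtap, 94.4 kb from Cdkn2a, lay at 0.69. Klhl9, Ifnz and Ifnab, 488.5 to 627.8 kb away, lay at -0.21, -0.53 and 2.78. Ifnab was itself not far above that floor in MEF, at -3.39 against -4.2. The 4 genes all lie on the lower-coordinate side, so a loss toward higher coordinates was not covered. A smaller deletion, or one of any size on that other side, stays open. Bmi1 was raised in these cells by design and is among the open explanations, untested.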

How the results depend on the processing

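Leaving out the 3 lines nearest to MEF, raising signals to the highest array floor and the slide term for the spheres were chosen after the results were seen. For iPS lines against MEF, 1802 genes passed with slide as a fixed block and 0 within the slide, where 1 residual degree of freedom remained; the 9 fits without 1 line gave 2402 to 3366, and the highest floor gave 1604 higher and 1233 lower, against 2074 and 700. For iPS lines against ES, normexp background gave 47 genes, quantile normalization 81, the stricter filter 2, the mean of all probes 1, the intensity trend 2 and the highest floor 307. The fits with slide as a fixed block, within the slide, with 8 groups, without the tail-tip lines, with the clone-number replicate block and without the 3 lines nearest to MEF gave 0, slide as a random block gave 7, and those without 1 line 0 to 8. For Bmi1-Oct4 against the hedgehog lines, no filter gave 2411 genes and the highest floor 330. For Shh against the small molecules, normexp gave 2, quantile normalization 32 and the highest floor 440. The highest floor gave 10 genes for oxysterol against purmorphamine and 21 for tail-tip against embryonic origin. Genes held at that floor on 6 arrays or more, whose spread the setting removes, made up 310 of 330, 397 of 440, 10 of 10 and 18 of 21 calls in these 4 comparisons and 278 of 307 against ES, but only 594 of 2837 against MEF. Leaving out 1 line gave 0 in each of these 4 comparisons. Limma with pooled spread called 699 genes for the spheres and 917 for ES against MEF, and the highest floor 7982 for the spheres. With an estimated correlation 4 gene lists were called. Against MEF, Cck turned to 1.15 with the stricter filter, which selects another probe, and with the mean of all probes Smo turned to 0.52, Gnas to 0.43 and Xist to -2.03. With the mean of all probes Hspa1a turned to -1.97 in the spheres and Cdc6 to -0.13 in ES against MEF; these reversals follow from the probes used. With slide as a fixed block Pcgf2 turned to -0.06 in the spheres. For the other changes the cause was not tested. For named genes against MEF, 1828 alternative values kept direction and side, 317 missed the threshold and 4 reversed. Against ES 149 stayed on the same side of the threshold and 88 missed it. The 149 include all 24 values each of Pou5f1, Nanog, Sox2 and Bmi1. These genes passed in no setting, and changes in their direction were not counted. By size, 1031 values for the spheres were the same, 251 moved and 2 reversed, and for ES against MEF 961, 193 and 1; normexp background moved 79 of the 130 genes named for the spheres. Dim signals limit the array floors, from -7.27 to -4.2 log2 units, and with them every bound.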

Other observations

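The Y-linked gene Ddx3y varied between lines in ways the groups do not follow. Ddx3y lay at -6.74 in purmorphamine-Oct4 line 1, -9.21 in the spheres, -3.64 in ES and -2.67 in oxysterol-Oct4 line 2, against 0.41 to 2.60 in the other 7 lines and 2.36 in MEF. Hprt lay at -0.73 in ES, 5.11 in MEF (saturated) and 4.01 in the spheres. Among the lines it lay at 2.74 in Bmi1-Oct4 line 1, 2.10 in purmorphamine-Oct4 line 2 and 2.37 in tail-tip line 2. In the other 6 lines it lay from -1.83 to 0.92. Cdkn2a lay at -6.24, -5.20 and -4.66 in the Bmi1-Oct4 lines and purmorphamine-Oct4 line 1, against -2.31 to -0.44 in the other 6. Among the named genes with several probes, 10 of 39 in iPS lines against MEF and 10 of 53 in spheres against MEF had probes more than 2-fold apart in opposite directions.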
